A study of Mus musculus with 15 samples.

How the data were processed

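Single-nucleus RNA was measured in the tibialis anterior muscle of 15 mice. Per the labels, mdx mice (C57BL/10ScSn-Dmdmdx/J, which lack full-length dystrophin) received an AAV2/9 vector carrying either a scrambled sequence or GDF5 in this muscle at 1 week of age, and tissue was taken 2 or 8 weeks later, at 3 or 9 weeks of age. Wild-type C57BL/6 mice were not injected, so genotype, substrain and injection change together between mdx and wild type. The titles of the older GDF5 libraries give 8 weeks and those of the older scrambled libraries 9; 8 was read as the time since injection, and an age gap of 1 week between these groups is not excluded. The groups were wild type at 3 weeks (2 libraries) and at 9 weeks (2), mdx with the scrambled vector at 3 weeks (2) and at 9 weeks (3), and mdx with the GDF5 vector at 3 weeks (3) and at 9 weeks (3).

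The submitters' processing notes state that reads from 10x Chromium nuclei libraries were mapped and counted with Cell Ranger 8.0.1 against mm10; they do not say whether intronic reads were counted. The deposited matrices hold counts, that is, UMI counts per gene and barcode with no normalization, for every annotated gene in the barcodes that Cell Ranger called as nuclei. Genes were placed with the GENCODE annotation of GRCm38 (mm10).

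Barcodes with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5 (expected rate 0.1); in the 11 of 15 libraries where the automatic threshold marked under 0.5% of barcodes, a score of 0.25 was used. All nuclei past the filters, called doublets included, were scaled to 10000 UMIs and log-transformed. Then 2000 variable genes chosen per library and ranked over libraries (without Gdf5, mitochondrial and sex-linked genes), 30 principal components, 15 neighbours and Leiden resolution 1 gave 26 clusters, with no batch integration. Called doublets were dropped after clustering. A cluster in which over 50% of nuclei had been called doublets (cluster 22) was removed, 22 clusters were named by marker genes as 11 classes, and 3 small clusters stayed unnamed. Intervals on UMI fractions and floors cover counting error only, while p-values measure the spread between samples.

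UMIs were summed per library for whole muscle (all nuclei kept), myonuclei, myogenic cells (satellite cells and myoblasts), fibro-adipogenic progenitors (mesenchymal cells of the interstitium), macrophages and endothelial cells. Myonuclei here took mature nuclei together with those of the neuromuscular and myotendinous junctions. A library with fewer than 20 nuclei of a class was left out of that class, so that in wild type, which had 4 or fewer such nuclei per library, myogenic cells could not be compared with mdx at these filters. Each class was fitted once over all groups with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F test, 1 mean per group, no block), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A group with 1 library in a class was assumed to vary like the others. CPM values, the usual unit of UMIs relative to a library total, were scaled with TMM factors where given with a fold change, and errors on log2 fold changes are standard errors from the F statistic. Numbers of nuclei per class were tested with edgeR with the log of the total as offset, adjusted over the classes. The CPM of Gdf5 was compared by an exact two-sided permutation test within each age. Gene lists, 24 in number and fixed with their members, were tested with camera from limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, which asks if a list's genes move on balance in one direction; lists needed at least 5 tested members.

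The groups, tests, gene lists, filters and the first set of alternatives were chosen before the data were examined. Named genes followed a rule also fixed then: Gdf5 and Dmd, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 4, no overlap between the groups and a name that is not a clone name (the 5 smallest p-values where fewer than 5 genes passed), and up to 4 members of each list by adjusted p. The text names those it needs; genes with a group at 3 or fewer counts were left out where a fold would depend on the prior count, and any gene outside the rule is said to be so.

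The numbers 1 to 3 of the labels were checked as possible pairs through the correlation of deviations from group means across 8728 genes. At 9 weeks the scrambled and GDF5 libraries with the same number had correlations of 0.300, 0.168 and 0.666, all over 0.1, so the blocked fit is given there beside results that it changes. This pairing comes from the data alone: the labels do not state a shared litter or day, GDF5 replicate 2 correlated slightly more with scrambled replicate 1 (0.200) than with its own number, and both replicates numbered 3 carry late library numbers (14 and 16).

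Sex was read from Xist and Y-linked transcripts: the libraries numbered 14, 15 and 16 had 1322, 1159 and 1191 CPM of Xist, and the other 12 libraries had 359 to 650 CPM of Y-linked genes with at most 0.529 CPM of Xist. These 3 libraries are replicate 3 of mdx scrambled at 9 weeks, mdx GDF5 at 3 weeks and mdx GDF5 at 9 weeks; counts were also made without them and with sex as a term.

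Alternatives covered DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, doublets kept, at least 1000 UMIs, a 20% mitochondrial limit, the replicate block, a fit of the compared groups only, other share denominators, and each library left out in turn. The pipeline was tested on simulated counts with 200 changed genes per comparison: edgeR recovered 0% to 30% of 2-fold and 7% to 91% of 4-fold changes with 0% to 20.5% of calls false, and DESeq2 in whole muscle and myonuclei had 16.8% to 27.1% of calls false. Camera with the preset correlation and fry called 21 of 21 changed and 0 of 21 unchanged lists at an unadjusted p under 0.05. The simulated genes were drawn independently of each other, so false calls for lists whose genes move together were not measured. The estimated correlation was not tried on simulated lists, so a list that it does not call may still have changed. Other software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3. None of the 12 pairs of replicate libraries held duplicated data: the chi-square per gene between members of a pair was 18.1 to 112.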

Results

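The 15 libraries held 170040 barcodes in all, 6904 to 26910 per library, with 20787712 to 34059405 UMIs each. After filtering, 74118 nuclei were kept, 917 to 8267 per library, with a median of 2693 to 4701 UMIs per nucleus. The share of barcodes that passed ran from 3.52% to 90.8%, and 85871 barcodes failed the mitochondrial limit of 5%, some of them other limits too. In wild type 26.1% and 3.52% passed at 3 weeks and 39.3% and 24.9% at 9 weeks, against 30.95% to 90.8% in mdx libraries. Mitochondrial UMIs were 5.84% to 17.5% in wild type and 1.20% to 7.19% in mdx. Library quality was thus not balanced between mdx and wild type. The thinnest library was wild type replicate 2 at 3 weeks, in which 948 of 26910 barcodes passed. The libraries numbered 14, 15 and 16 (replicate 3 of mdx scrambled at 9 weeks, of mdx GDF5 at 3 weeks and of mdx GDF5 at 9 weeks) came from female mice by their Xist transcript, and the other 12 from males.

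The first question was whether the vector raised its own transcript. Gdf5 (ENSMUSG00000038259, GRCm38 chromosome 2, 155941023 to 155945367), which codes for a secreted ligand of the BMP family, stood at 27.5 ± 21.1 CPM (SD, n = 3) with the GDF5 vector at 3 weeks, against 0.134 ± 0.0559 CPM (n = 2) with the scrambled vector, a ratio of 206. Reads of the vector count here only where its sequence matches the mouse gene, so these levels hold for the part that maps. Replicates 1 and 2 had 40.8 and 38.5 CPM, and replicate 3 had 3.23 CPM. At 9 weeks the 3 GDF5 libraries had 14.7, 10.6 and 3.86 CPM (mean 9.73 ± 5.50 SD), and the scrambled libraries had 0 of 64197763 UMIs, so that the transcript was at least 208-fold higher against a floor of 3 counts over the group. With fewer UMIs under that floor the bound was 108 without scrambled replicate 1 and 134 without scrambled replicate 2. By class, Gdf5 at 9 weeks stood at 12.4 ± 7.93 CPM (SD, n = 3) in myonuclei, 4.25 ± 0.930 in myogenic cells, 2.43 ± 4.21 in progenitors and 1.05 ± 0.932 in macrophages, with 0 of 956263 UMIs in endothelial cells. At 3 weeks it stood at 28.2 ± 21.3 CPM in myonuclei, 44.4 ± 40.9 in myogenic cells (6 UMIs), 10.6 ± 13.5 in progenitors (10 UMIs), 7.40 ± 12.8 in macrophages (10 UMIs) and 38.4 ± 66.5 in endothelial cells (9 UMIs). Free RNA was not subtracted from these levels, so they do not show which classes make the transcript. Every GDF5 library exceeded every scrambled library at both ages. The exact two-sided permutation p was 0.2 at 3 weeks and 0.1 at 9 weeks, where 0.1 is the smallest that either design allows. Adjusted over all genes, Gdf5 did not pass in whole muscle at either age (edgeR adjusted p = 1 and 0.509). Without replicate 3 the GDF5 mean exceeded the scrambled mean by 39.5 CPM at 3 weeks, and by 27.4 with it.

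**Figure D1:**
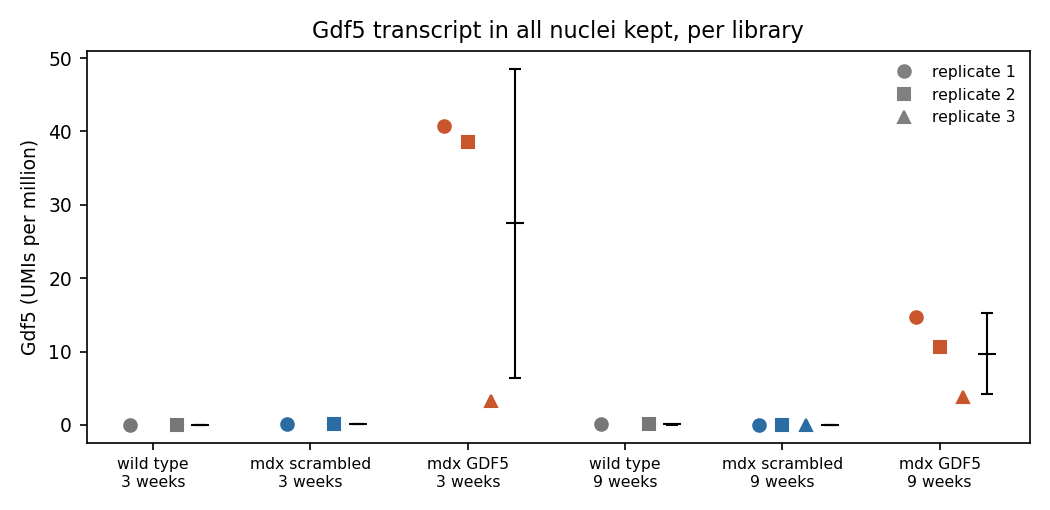
Gdf5 transcript in CPM over all nuclei kept, 1 symbol per library, with group means and SD in black. All 6 GDF5 libraries lie above all scrambled and wild-type libraries, and the third replicates (3.23 and 3.86) lie lowest in their groups.

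Shares of cell classes differed between mdx and wild-type muscle at 9 weeks. Nuclei of regenerating fibres made up 10.3% ± 1.84 (SD, n = 3) of mdx scrambled nuclei at 9 weeks against 0.0330% ± 0.00823 (n = 2) of wild-type nuclei, a log2 ratio of 8.22 ± 1.27 (SE, adjusted p = 0.0004). That fitted ratio rests on 1 such nucleus in each wild-type library, with exact Clopper-Pearson intervals (95%) of 0.000688% to 0.151% and 0.000983% to 0.216%. Macrophages were 15.1% ± 4.23 against 0.132% ± 0.0329 (6.83 ± 1.33, adjusted p = 0.00151), and myogenic nuclei 7.03% ± 7.21 against 0.0738% ± 0.0494 (6.47 ± 1.74, adjusted p = 0.0116). Mural cells, which wrap small vessels, fell (−1.83 ± 0.65, adjusted p = 0.0451). Mature myonuclei were 55.7% of mdx scrambled nuclei at 9 weeks and 92.8% of wild-type nuclei. With 1 library left out the log2 ratio of myogenic nuclei stayed between 5.19 and 7.41, but its call was lost without wild type replicate 1 or replicate 2, and the number of classes called went from 4 to 2 without either. The myogenic share of wild type rests on the mitochondrial limit and on the removal of cluster 22. At a limit of 20% in place of 5% it was 3.39% and 3.72% in the 9-week wild-type libraries, and the log2 ratio was 1.28 (adjusted p = 0.0380). Cluster 22, removed because 61.5% of its nuclei had been called doublets, had satellite cell genes such as Calcr and Chodl among its leading genes. With its nuclei that were not called doublets kept as myogenic the share was 0.783% and 0.848% in those libraries and the log2 ratio 3.13 (adjusted p = 0.0379). Myogenic cells of mdx and wild type, which had too few nuclei for a test of genes, could then be compared at 9 weeks. In that comparison 944 genes were called with cluster 22 kept, 920 with doublets kept and 339 at the 20% limit. When kept, cluster 22 held 25 of 29 and 21 of 22 wild-type nuclei, but 13 of 1274, 1 of 188 and 4 of 58 mdx scrambled nuclei. With doublets kept it held 32 of 36 and 21 of 22 wild-type nuclei. The 944 and 920 genes thus set different clusters against each other, and cluster and genotype are not separated.

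At 3 weeks no class differed between mdx scrambled (n = 2) and wild type (n = 2) by edgeR, with myogenic (5.05 ± 1.88), macrophage (3.19 ± 1.21) and myotendinous junction nuclei (1.52 ± 0.57) at unadjusted p under 0.05 and an adjusted p of 0.0832 each. Without mdx scrambled replicate 2, 1 class passed, and at the 20% mitochondrial limit 4 classes passed while the myogenic log2 ratio was 0.08. With cluster 22 kept that ratio was 0.64 and the wild-type share 0.897% and 1.82%. Between 3 and 9 weeks in mdx scrambled muscle, nuclei of regenerating fibres had a log2 ratio of 3.17 ± 0.91 (adjusted p = 0.0525) and no class passed, with 2 classes at unadjusted p under 0.05. Without mdx scrambled replicate 1 at 3 weeks, 2 classes passed.

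Myogenic nuclei, which hold the satellite cells that the series is about, were not called different in share between the vectors at either age. At 9 weeks they were 6.14% ± 2.40 (SD, n = 3) with GDF5, from 3.39% to 7.76%, and 7.03% ± 7.21 (n = 3) with the scrambled vector, from 1.80% to 15.3%, a log2 ratio of −0.20 ± 1.08 (SE, adjusted p = 0.955). The direction turned to 1.08 without scrambled replicate 1 and to 0.09 without GDF5 replicate 3. At 3 weeks they were 1.65% ± 2.03 (n = 3) against 1.77% ± 2.19 (n = 2), a log2 ratio of −0.12 ± 1.21 (adjusted p = 0.988), which turned to 2.86 without scrambled replicate 2, 0.28 without GDF5 replicate 1 and 0.34 without GDF5 replicate 2. The 3-week shares rest on the mitochondrial limit too. At 20% in place of 5% they were 4.44%, 4.97% and 6.93% with GDF5 and 3.50% and 4.92% with the scrambled vector. Scrambled replicate 1 had 6 such nuclei at 5% and 277 at 20%. Cluster 22, left out of this class, held 50, 50 and 5 nuclei not called doublets in the GDF5 libraries at 3 weeks. In the scrambled libraries at that age it held 12 and 8. Nuclei of regenerating fibres at 9 weeks were 5.62% ± 0.305 with GDF5 and 10.3% ± 1.84 with the scrambled vector, with no overlap between the groups, as chance gives for 10% of classes at 3 against 3 (log2 −0.88 ± 0.71, adjusted p = 0.656). Macrophages were 9.36% ± 5.38 against 15.1% ± 4.23 (−0.69 ± 0.83, adjusted p = 0.887). By edgeR 0 of 11 classes passed at either age, with 0 at an unadjusted p under 0.05 at 3 weeks and 0 at 9 weeks. With the replicate block at 9 weeks 0 passed too and 1 had an unadjusted p under 0.05, lymphatic endothelial nuclei (2.22 ± 0.95, adjusted p = 0.461). In all 3 pairs by number, nuclei of regenerating fibres were lower with GDF5, and mature, myotendinous junction, progenitor, endothelial and lymphatic endothelial nuclei higher, 6 of 11 classes where chance gives 2.75 if classes were independent. Shares of 1 library depend on each other.

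**Figure D2:**
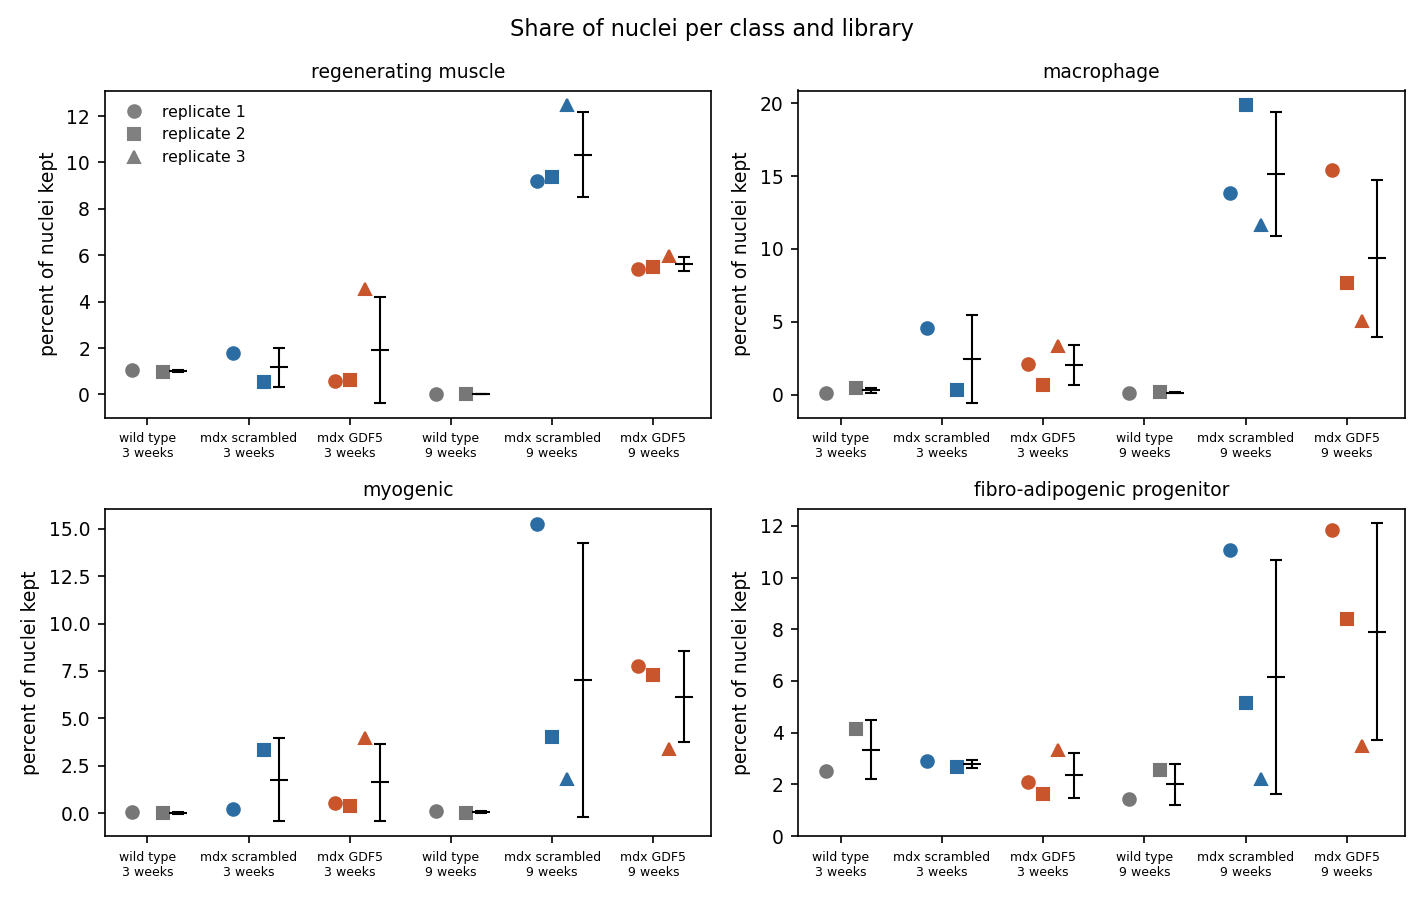
Percent of nuclei kept in 4 classes per library, with group means and SD in black. At 9 weeks all mdx libraries lie above both wild-type libraries for regenerating muscle and macrophages, and the GDF5 libraries (5.39% to 5.96%) lie below the scrambled ones (9.18% to 12.5%) for regenerating muscle.

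Muscle of mdx mice at 3 weeks was compared with wild type to see the disease at its start. In myonuclei, Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149), a transcription factor induced when muscle loses its nerve, rose by a log2 fold change of 3.28 ± 0.45 (SE, n = 2 against 2), from 5.95 ± 1.8 to 60.8 ± 15 CPM (SD). The myonuclei compared lay in different clusters, 63.3% and 24.5% of wild-type nuclei in clusters 21 and 23 and 42.2% and 39.0% of mdx scrambled nuclei in clusters 0 and 1. Actc1 (ENSMUSG00000068614, chromosome 2, 114047282 to 114053548), the cardiac actin that developing skeletal muscle also makes, fell by 3.63 ± 0.52 on the log2 scale. Mstn (ENSMUSG00000026100, chromosome 1, 53061640 to 53068079), which codes for the growth inhibitor myostatin, rose by 2.61 ± 0.59. Its level went from 8.33 ± 0.24 to 51.3 ± 7.5 CPM. Utrn (ENSMUSG00000019820, chromosome 10, 12382188 to 12869365), the autosomal relative of dystrophin, rose by 1.74 ± 0.35. The immediate early nuclear receptors Nr4a1 (2.47 ± 0.53), Nr4a2 (3.88 ± 0.78) and Nr4a3 (5.20 ± 1.02) rose, as did the kinase gene Sik1 (5.50 ± 0.76). The metallothioneins Mt1 (4.81 ± 1.19) and Mt2 (6.35 ± 1.31) rose, and so did Ankrd1 (4.61 ± 1.11), which responds to stretch, and Gabrr2 (4.12 ± 1.04). Myoglobin (Mb, −3.30 ± 0.87), the fatty acid carrier Fabp4 (−2.78 ± 0.71), Rcan2 (−1.91 ± 0.30) and Rmdn1 (−1.98 ± 0.36) fell. Dmd itself (ENSMUSG00000045103, chromosome X, 82948870 to 85206141), whose mdx lesion is a point mutation, had a log2 fold change of 0.78 ± 0.35 (adjusted p = 0.185).

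Several of the lists fixed in advance lay mostly on 1 side of 0 in myonuclei at 3 weeks. Of 20 genes of atrophy and autophagy 19 lay above 0 (median 1.07), with 3 past the test over all genes and 10 up and 1 down adjusted over the list alone (camera adjusted p = 1.49e-06, adjusted p = 0.437 with an estimated correlation). Of 17 genes of the dystrophin complex 15 lay above 0 (median 0.55), 5 rose over all genes and 7 adjusted over the list alone, among them Utrn, Sgcd (1.08 ± 0.26) and Itga7 (1.48 ± 0.37), with adjusted p = 0.298 with an estimated correlation. For the BMP response 14 of 15 lay above 0 (median 0.74) and 3 rose over all genes and 3 adjusted over the list alone, such as Tgif1 (2.12 ± 0.41), with adjusted p = 0.298 with an estimated correlation. All 15 angiogenesis genes lay below 0 (median −1.07), where Kdr (−2.79 ± 0.70) and Eng (−2.39 ± 0.52), receptors of endothelial cells, fell over all genes and 4 fell adjusted over the list alone (adjusted p = 0.298 with an estimated correlation). Endothelial nuclei were 1.82% of wild-type and 0.709% of mdx scrambled nuclei, a difference that did not pass (adjusted p = 0.280). Markers of other cells moved as well, with 17 of 21 macrophage genes above 0 (median 1.41) and 2 past the test over all genes, a list that camera did not call (adjusted p = 0.216). The median of the RNA quality list was −0.59 in myonuclei, with 11 of 12 members below 0 (camera adjusted p = 0.105). In whole muscle it was −0.63, with 11 of 12 members below 0 (camera adjusted p = 0.0358, adjusted p = 0.704 with an estimated correlation). In all 8 lists were higher and 1 lower in myonuclei by camera, 2 and 1 by fry, and 0 held with an estimated correlation.

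In number, 417 genes rose and 361 fell in myonuclei at 3 weeks of 15713 tested, and 140 rose and 172 fell in whole muscle of 17711. In whole muscle these included Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929; 7.39 ± 1.63), a gene of lipid-laden macrophages, Hmga2 (6.31 ± 1.44) and Runx1 (3.404 ± 0.73), while mitochondrial creatine kinase (Ckmt2, −1.93 ± 0.31) and Actg1 (−1.84 ± 0.40) fell. With 2 libraries a side these counts moved with each library. Those of myonuclei went from 778 to 213 without mdx scrambled replicate 1, 87 without mdx scrambled replicate 2, 260 without wild type replicate 1 and 25 without wild type replicate 2, and those of whole muscle from 312 to 27, 117, 52 and 4 in the same order. DESeq2 called 837 up and 779 down in myonuclei and 808 up and 738 down in whole muscle.

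At 9 weeks mdx scrambled muscle was again compared with wild type. In whole muscle Gpnmb (8.98 ± 1.59 on the log2 scale, SE, n = 3 against 2) rose from 0.423 to 205 ± 92 CPM (SD), the lysosomal protease gene Ctss by 7.30 ± 1.24, and the monocyte receptor Ccr2 by 4.71 ± 0.74. Embryonic myosin (Myh3, ENSMUSG00000020908, chromosome 11, 67078300 to 67102291), a marker of newly formed fibres, rose by 7.91 ± 1.83, from 0.211 ± 0.081 to 49.5 ± 52 CPM, and the fetal acetylcholine receptor subunit Chrng by 5.50 ± 1.09. Pax7 (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528), the satellite cell transcription factor, rose by 3.72 ± 0.61, from 6.40 ± 2.6 to 85.9 ± 63 CPM, and Fgfr4 by 4.70 ± 0.77. Tgfb1 (3.94 ± 0.80) and Fn1 (2.45 ± 0.74), which code for a profibrotic cytokine and for fibronectin, rose as well. Among genes that fell were Mogat2 (ENSMUSG00000052396, chromosome 7, 99219084 to 99238619; −4.94 ± 0.56), an acyltransferase of triglyceride synthesis, the heart-type fatty acid binding protein Fabp3 (−3.55 ± 0.65) and the muscle cytochrome oxidase subunit Cox6a2 (−3.56 ± 0.68). The classes of nuclei moved with these genes, since mature myonuclei were 55.7% of mdx scrambled and 92.8% of wild-type nuclei.

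Gene groups in whole muscle at 9 weeks split between repair and immune genes above and contractile and metabolic genes below. All 20 cell cycle genes lay above 0 (median 3.74) and 17 rose over all genes (18 adjusted over the list alone), such as Mki67 (3.80 ± 0.78) and Anln (4.19 ± 0.70), with adjusted p = 0.359 with an estimated correlation. Of 25 interferon response genes 24 lay above 0 (median 2.46) and 18 rose (21 adjusted over the list alone), with Trim30a (3.66 ± 0.54), Stat2 (1.99 ± 0.30) and Irf1 (2.38 ± 0.43) among them (adjusted p = 0.359 with an estimated correlation). Of 19 quiescent satellite cell genes 12 rose, Pax7 and Fgfr4 among them (12 adjusted over the list alone, median 2.42), with adjusted p = 0.341 with an estimated correlation. Of 14 genes of activated myoblasts 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 2.47), such as Rassf4 (4.23 ± 0.51) and Hmga2 (7.60 ± 1.36), with adjusted p = 0.330 with an estimated correlation. Of 19 genes of regenerating fibres 15 rose and 1 fell (16 and 1 adjusted over the list alone, median 3.84), with adjusted p = 0.341 with an estimated correlation. Of the 18 tested features of fast glycolytic fibres, where 1 symbol has a pair of identifiers, 16 fell (median −1.26), such as Tnni2 (−1.84 ± 0.38) and Ampd1 (−1.37 ± 0.30) (adjusted p = 0.341 with an estimated correlation). Of 20 genes of fatty acid and mitochondrial metabolism 12 fell (13 adjusted over the list alone), such as Hadhb (−1.52 ± 0.24) and Cpt1b (−1.16 ± 0.24), with adjusted p = 0.359 with an estimated correlation. The RNA quality list was lower too (median −1.09, with 7 fallen and 1 risen of 12, adjusted p = 0.420 with an estimated correlation). By camera 9 lists were higher and 4 lower, by fry 9 and 4, and 0 with an estimated correlation.

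**Figure D3:**
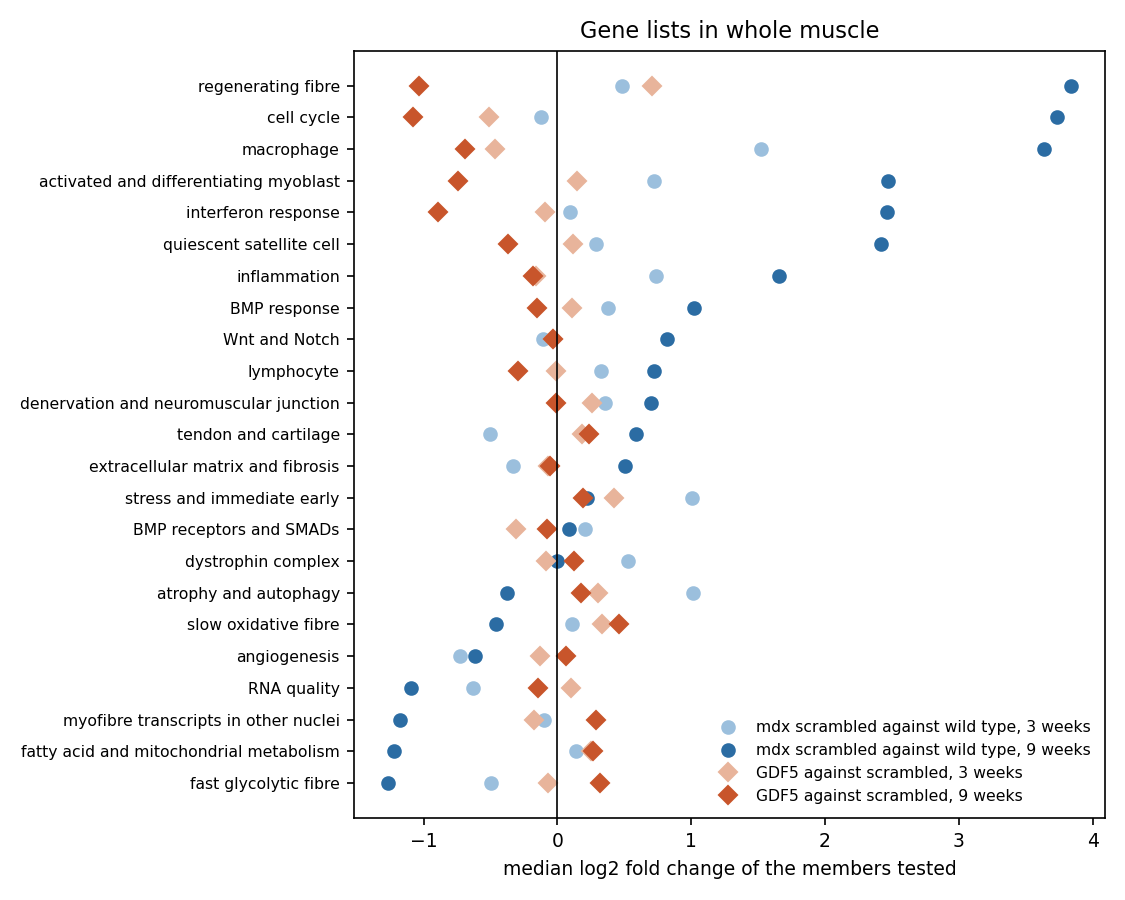
Median log2 fold change of each gene list in whole muscle for mdx scrambled against wild type (circles) and GDF5 against scrambled (diamonds) at both ages. At 9 weeks the cell cycle and interferon lists lie at 3.74 and 2.46 for mdx scrambled against wild type and at −1.08 and −0.89 for GDF5 against scrambled. Both comparisons share the scrambled libraries, so these values are not independent.

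In myonuclei at 9 weeks, junction nuclei included, Runx1 was again high (5.04 ± 0.46 on the log2 scale, adjusted p = 0.000263). It stood at 272 ± 41 CPM (SD, n = 3) against 8.31 ± 0.25 (n = 2). Here too the groups lay in different clusters, with 59.1% and 28.9% of wild-type nuclei in clusters 21 and 23, which held 0.236% and 0.207% of mdx scrambled nuclei. Glis3 (4.86 ± 0.61), the protocadherin gene Pcdh7 (4.65 ± 0.71), the kinase gene Cdk14 (4.59 ± 1.01) and the microtubule gene Map1b (4.49 ± 0.63) rose, while Mogat2 (−4.01 ± 0.47), Fabp3 (−2.91 ± 0.62), Wnt5a (−1.84 ± 0.31) and the transcriptional cofactor Dach2 (−3.63 ± 0.58) fell. Of 22 genes of denervation and the neuromuscular junction 10 rose and 1 fell (12 and 1 adjusted over the list alone, median 1.23), with Ncam1 (2.49 ± 0.39) and Chrnb1 (1.44 ± 0.29) rising beside Runx1. Neuromuscular junction nuclei were 0.986% ± 0.64 (SD, n = 3) of all mdx scrambled nuclei kept and 0.544% (n = 2) of wild-type nuclei. The list was not tested without them. Of 18 genes of regenerating fibres 10 rose and 1 fell (median 3.03, or 3.01 with genes at 0 set to their bound), such as Igf2 (3.61 ± 0.67) and neonatal myosin Myh8 (3.93 ± 0.81). The adjusted p = 0.198 with an estimated correlation for both lists. Of 17 dystrophin complex genes 7 rose (8 adjusted over the list alone), among them Utrn (2.35 ± 0.34), Sntb2 (2.36 ± 0.31) and Itga7 (2.27 ± 0.36), and of 15 BMP response genes 3 rose (5 adjusted over the list alone), such as Ski (0.87 ± 0.18), with adjusted p = 0.192 and 0.198 with an estimated correlation. Red blood cell RNA moved with genotype, since Hbb-bs fell by 4.91 ± 1.01 on the log2 scale in myonuclei. Transcripts of other cells moved as well: 18 of 21 macrophage genes lay above 0 (median 2.15) and 5 rose (9 adjusted over the list alone), with camera adjusted p = 0.000211 and adjusted p = 0.450 with an estimated correlation. The RNA quality (median −0.97) and angiogenesis lists (−1.10) were lower by camera, both with adjusted p = 0.450 with an estimated correlation. By fry 6 lists were higher and 1 lower.

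In all 3206 genes rose and 2799 fell in whole muscle at 9 weeks, and 962 rose and 1021 fell in myonuclei (DESeq2 3850, 2873, 1340 and 1291). The whole-muscle count of 6005 went to 2495 without wild type replicate 1 and 3675 without wild type replicate 2. That of myonuclei, 1983, went to 876 without wild type replicate 1, 272 without wild type replicate 2 and 856 without mdx scrambled replicate 2. Of the genes called in myonuclei at 3 weeks, 184 of 417 rose at 9 weeks too, where lists drawn independently would share 25.5, and 184 of 361 fell (23.5 if independent).

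To follow disease with age, mdx scrambled muscle at 9 weeks (n = 3) was compared with 3 weeks (n = 2), with no wild-type term. In myonuclei Mstn fell by 2.93 ± 0.50 on the log2 scale (SE), from 51.3 ± 7.5 to 6.85 ± 2.7 CPM (SD). The myonuclei of the ages lay in different clusters: clusters 0 and 1 held 42.2% and 39.0% of nuclei at 3 weeks and 0.0334% and 0.115% at 9 weeks, when the leading clusters were 7 and 15 (18.5% and 14.8%). The imprinted noncoding RNAs Meg3 (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726; −4.69 ± 0.81), Rian (−4.81 ± 0.91) and Mirg (−5.24 ± 0.91), which lie in 1 locus, fell together. Cluster 19, with 131 nuclei at 3 weeks and 3 at 9 weeks, held 74.3% and 81.2% of Meg3 counts in the 3-week libraries. In the other myonuclei Meg3 went from 209 ± 26.0 to 23.9 ± 5.44 CPM and Mirg from 6.25 ± 0.433 to 0.793 ± 0.104 CPM. The neuregulin receptor gene Erbb4 (−3.97 ± 0.66), Gabrr2 (−4.71 ± 0.89) and Hbb-bs (−7.09 ± 1.09), a red blood cell transcript, fell as well. Runx1 (2.17 ± 0.39), the immunoglobulin-domain protein gene Igfn1 (ENSMUSG00000051985, chromosome 1, 135953578 to 136006342; 2.73 ± 0.46), Rcan2 (1.68 ± 0.28), Mylk4 (1.53 ± 0.30) and the collagen receptor Ddr2 (3.07 ± 0.61) rose. The adjusted p of these genes was 0.0430 or 0.0462, and 30 genes rose and 118 fell in all (DESeq2 432 and 588). This call was lost, with 0 genes, without scrambled replicate 1 or 2 at 3 weeks or replicate 1, 2 or 3 at 9 weeks, and at a mitochondrial limit of 20%. Of 17 stress and immediate early genes 16 lay below 0 (median −0.83) and camera placed the list lower, with adjusted p = 0.836 with an estimated correlation.

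In myogenic cells of mdx scrambled muscle 3 libraries at 9 weeks were set against the 1 library with at least 20 such nuclei at 3 weeks, so that age and that library's own deviation are not separated. Against that library Cd34, a surface marker of quiescent satellite cells, was lower by 2.63 ± 0.47 on the log2 scale (SE), Klf15 by 3.20 ± 0.59 and Dgkg by 5.50 ± 0.74. Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544; 3.46 ± 0.66), Runx1 (2.32 ± 0.49), Runx2 (3.84 ± 0.57) and Hmga2 (3.39 ± 0.72) were higher. Of 23 extracellular matrix genes 20 lay above 0 (median 2.11, or 1.72 with genes at 0 set to their bound) and 5 passed (9 adjusted over the list alone), with camera adjusted p = 2.40e-08 and adjusted p = 0.338 with an estimated correlation. All 10 macrophage genes tested lay above 0 too (median 1.89, or 1.83 at the bound) and 13 of 14 myofibre transcripts below 0 (median −0.87), each with adjusted p = 0.454 with an estimated correlation. The quiescent satellite cell list had a median of 0.03, a mean of −0.24 and a test direction of down, so these differed in sign. In all 91 genes were called higher and 134 lower (DESeq2 66 and 46), and the count of 225 went to 81 without scrambled replicate 1 at 9 weeks and to 3 with cluster 22 kept.

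The GDF5 vector was compared with the scrambled vector at 3 weeks, 2 weeks after injection, to see its early effect on muscle (n = 3 against 2). The gene with the smallest p in both whole muscle and myonuclei was Igfn1, at 87.9 ± 24 CPM (SD) with GDF5 and 14.8 ± 6.7 CPM with the scrambled vector in whole muscle, a log2 fold change of 2.55 ± 0.41 (SE) that did not pass (adjusted p = 0.710). The apoptosis-linked kinase gene Dapk2 (2.06 ± 0.53) was higher in all GDF5 libraries, and Tmem233 (−1.41 ± 0.37), Lsmem1 (−1.19 ± 0.30) and the Z-disc gene Myoz3 (−0.92 ± 0.24) lower, none past the test. In fibro-adipogenic progenitors Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), which codes for the joint lubricant lubricin, stood at 125 ± 53 against 14.1 ± 1.3 CPM (3.11 ± 0.63, adjusted p = 0.385). Mn1 (1.79 ± 0.33), Nedd9 (1.60 ± 0.35) and Dapk2 (2.81 ± 0.63) were higher there and the glypican gene Gpc4 (−1.29 ± 0.26) lower, again short of the threshold. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), a target of the glucocorticoid receptor singled out after its values were seen, had 590 ± 222 CPM (SD) against 152 ± 133 CPM in whole muscle (1.96 ± 0.92, adjusted p = 1).

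Gene lists at 3 weeks gave no shift that held by fry or with an estimated correlation in any class. In whole muscle 15 of 19 genes of regenerating fibres lay above 0 (median 0.71), with 17 of 22 of the neuromuscular junction list (0.26) and 16 of 20 stress genes (0.42), and 9 of 12 BMP receptors and SMADs lay below 0 (median −0.31). The BMP response list, genes downstream of the receptor family that GDF5 binds, had a median of 0.11 in whole muscle (camera adjusted p = 0.0734) and of 0.45 in myonuclei with 12 of 15 above 0 (camera adjusted p = 0.0124, adjusted p = 0.778 with an estimated correlation). In progenitors the 5 tendon and cartilage genes had a median of 0.60, with 1 past the test adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). By camera 5 lists were higher and 2 lower in whole muscle, all with adjusted p = 0.777 with an estimated correlation, and 0 moved by fry. GDF5 replicate 3 at 3 weeks stood apart from its group and lay nearer the 9-week libraries, and 4.54% of its nuclei were of regenerating fibres against 0.602% in the lowest library of its group.

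In number, 0 genes passed at 3 weeks by edgeR in whole muscle (505 at an unadjusted p under 0.05; DESeq2 2 up and 2 down), myonuclei (643; 3 and 3), myogenic cells (694; 0 and 0, 1 scrambled library) and progenitors (407; 0 and 0). Without GDF5 replicate 3, 1 gene passed in whole muscle, 2 in myonuclei and 3 in myogenic cells, where 2 passed without GDF5 replicate 1 and 8 without GDF5 replicate 2, and without scrambled replicate 1, 1 passed in progenitors. In macrophages Sox5 (ENSMUSG00000041540, chromosome 6, 143828425 to 144781977), a transcription factor of cartilage, fell by 3.49 ± 0.45 (adjusted p = 0.0224), from 57.5 ± 7.7 to 5.79 ± 1.5 CPM. That call was lost, with 0 genes, without GDF5 replicate 1, 2 or 3, with doublets kept and at a mitochondrial limit of 20%. Without scrambled replicate 1, 159 genes passed in macrophages, Sox5 not among them. DESeq2 called 10 up and 85 down there with all libraries, and 774 genes had an unadjusted p under 0.05. In endothelial cells 4 haemoglobin genes, Hbb-bt (ENSMUSG00000073940, chromosome 7, 103812524 to 103813996; −5.995 ± 0.62), Hbb-bs (−5.59 ± 0.73), Hba-a1 (−5.96 ± 0.74) and Hba-a2 (−6.46 ± 0.84), were called lower than in the 1 scrambled library with at least 20 such nuclei, and 0 passed at the 20% mitochondrial limit. These transcripts belong to red blood cells, and with 1 library the spread of the scrambled group is unknown.

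At 9 weeks, 8 weeks after injection, the GDF5 and scrambled groups (n = 3 each) were compared for the lasting effect of the vector. Igfn1 was again the gene with the smallest p in whole muscle, at 239 ± 38 CPM (SD) with GDF5 against 61.8 ± 25 CPM (log2 1.95 ± 0.34 SE, adjusted p = 0.509). It was also higher in myonuclei (1.74 ± 0.37) and macrophages (2.43 ± 0.36, adjusted p = 0.0954). The macrophage cluster held 14.5 CPM of Igfn1 against 256 and 506 CPM in myonucleus clusters 7 and 13, and myofibre transcripts lay higher in macrophages in this comparison (median 0.67, adjusted p = 0.284 with an estimated correlation). The muscle deaminase relative Apobec2 (1.04 ± 0.21) was higher in whole muscle. Meg3 stood at 287 ± 126 against 36.0 ± 15 CPM in myonuclei (3.00 ± 0.72) and Mirg at a log2 fold change of 3.52 ± 0.84. Of Meg3 counts in the GDF5 libraries 73.2% to 89.9% came from cluster 19, a myonucleus cluster of 67 nuclei in these libraries and 3 in the scrambled ones. In the other myonuclei Meg3 stood at 40.7 ± 6.84 against 23.9 ± 5.44 CPM. In progenitors the ceramide glucosyltransferase gene Ugcg (ENSMUSG00000028381, chromosome 4, 59189257 to 59222833; −1.51 ± 0.25, adjusted p = 0.137) and the cytokine gene Il34 (−1.23 ± 0.28) were lower. Prg4 (1.89 ± 0.48), Mn1 (1.11 ± 0.25) and the matricellular gene Ccn2 (1.63 ± 0.38) were higher. None of these passed.

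Myogenic cells at 9 weeks are where the vector's effect on satellite cells would be read. Fkbp5 stood at 691 ± 188 CPM (SD, n = 3) with GDF5 against 225 ± 84 CPM (n = 3), a log2 fold change of 1.68 ± 0.31 (SE). Usp2 (ENSMUSG00000032010, chromosome 9, 44067021 to 44095627), a ubiquitin protease, stood at 124 ± 12 against 40.3 ± 4.0 CPM (1.53 ± 0.28), and each had adjusted p = 0.0646. Fgf1 (1.98 ± 0.39) and Serpini1 (1.52 ± 0.32) were higher in all GDF5 libraries and did not pass without the block described next. Pax7, singled out after its values were seen, did not differ, at a log2 fold change of −0.05 ± 0.27. With the replicate number as a block, 22 genes passed, 18 up and 4 down, against 0 without it, with Usp2 at 1.62 ± 0.30 (adjusted p = 0.00468), Fkbp5 at 1.65 ± 0.30 (adjusted p = 0.00542), Serpini1 at 1.57 ± 0.32 (adjusted p = 0.0150) and Fgf1 at 1.96 ± 0.44 (adjusted p = 0.0268). Without the libraries numbered 14 to 16, 74 genes passed, 48 up and 26 down, and with sex as a term, chosen after seeing the data, 23. These fits called 18 genes in common with the block, the 4 named here among them. They are not independent checks, since the female libraries are replicate 3 of both groups, and 0 genes passed by DESeq2, with doublets kept or at the 20% mitochondrial limit. Free RNA from fibres was not subtracted. The rises called without libraries 14 to 16 include the fibre genes Myh4 (0.85), Tcap (1.09) and Cox6a2 (1.61), which the block did not call. In pooled myonuclei of the 9-week GDF5 libraries Usp2 stood at 772 CPM, above its myogenic level, and Fkbp5 at 382 CPM, below it. Under the block 1 gene, Gdf5, passed in myonuclei and 1 gene in macrophages, against 0 in each without it. Without scrambled replicate 2, 5 genes passed in myogenic cells, 3 without scrambled replicate 3 and 1 without GDF5 replicate 3.

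Gene lists at 9 weeks were tested between the vectors, with the same scrambled libraries that the comparison with wild type used. In whole muscle all 25 interferon response genes lay below 0 (median −0.89, camera adjusted p = 1.87e-12, adjusted p = 0.654 with an estimated correlation), as did 17 of 18 in myonuclei (−0.57) and all 12 tested in progenitors (−0.50), with adjusted p = 0.631 and 0.325 with an estimated correlation. In macrophages the median was −0.40 and in myogenic cells −0.14 (adjusted p = 0.602 and 0.438 with an estimated correlation), but in endothelial cells it was 0.13, with 7 of 13 above 0. All 20 cell cycle genes lay below 0 in whole muscle (median −1.08, adjusted p = 0.711 with an estimated correlation), Mki67 among them (−1.27 ± 0.56, adjusted p = 0.743). Of 19 genes of regenerating fibres 16 lay below 0 (median −1.03), of 14 of activated myoblasts 13 (−0.74) and of 22 macrophage genes 18 (−0.69) (adjusted p = 0.884, 0.654 and 0.884 with an estimated correlation). Above 0 lay 16 of 18 features of fast glycolytic fibres (0.32) and 16 of 20 genes of fatty acid metabolism (0.26), with adjusted p = 0.864 and 0.884 with an estimated correlation. In these libraries macrophages were 9.36% with GDF5 and 15.1% with the scrambled vector, and nuclei of regenerating fibres 5.62% and 10.3%. All 14 tested myofibre transcripts lay above 0 in progenitors (median 0.75) and in macrophages (0.67), cells that do not make them, with adjusted p = 0.253 and 0.284 with an estimated correlation. The BMP response (median −0.15, camera adjusted p = 0.863) and the quiescent satellite cell list (−0.37, 0.438) were not called in whole muscle. No list gene passed over all genes, and 0 lists held with an estimated correlation or moved by fry. The replicate block, added for lists after seeing the data, changed some camera calls. Lists higher and lower went from 3 and 5 to 3 and 4 in whole muscle and from 6 and 3 to 6 and 4 in progenitors. They went from 2 and 3 to 3 and 3 in myogenic cells and from 0 and 0 to 1 and 0 in endothelial cells. With the block 0 lists held with an estimated correlation or by fry. Without the libraries numbered 14 to 16, an alternative chosen after seeing the data, the medians were −0.54 (interferon), −0.72 (cell cycle), −0.63 (regenerating fibre), −0.48 (activated myoblast) and −0.38 (macrophage), and camera no longer called the last pair of lists (adjusted p = 0.112 and 0.288). The interferon median was then −0.07 in progenitors (5 of 8 below 0), 0.03 in myogenic cells and 0.22 in endothelial cells, but −0.51 in myonuclei (17 of 19 below 0) and −0.16 in macrophages (15 of 20).

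At 9 weeks edgeR called 0 genes in each class: whole muscle (1091 at an unadjusted p under 0.05; DESeq2 9 up and 4 down), myonuclei (600; 4 and 1), myogenic cells (371; 0 and 0), progenitors (380; 0 and 1), macrophages (258; 1 and 0) and endothelial cells (177; 0 and 0). The groups did not overlap for 13.6% of genes in whole muscle, 11.03% in myonuclei, 11.1% in myogenic cells, 14.4% in progenitors and 7.93% in macrophages, where chance gives 10%. Without scrambled replicate 3, 4 genes passed in myonuclei, and without GDF5 replicate 3, 1 gene passed in macrophages. The test of whether the effect of GDF5 differed between the ages called 0 genes by edgeR in myonuclei, myogenic cells and progenitors (270, 637 and 237 at an unadjusted p under 0.05; DESeq2 0 in each). In myogenic cells 8 genes passed that test without GDF5 replicate 2 at 3 weeks, 1 without GDF5 replicate 1 at 3 weeks and 1 without GDF5 replicate 3 at 9 weeks.

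**Figure D4:**
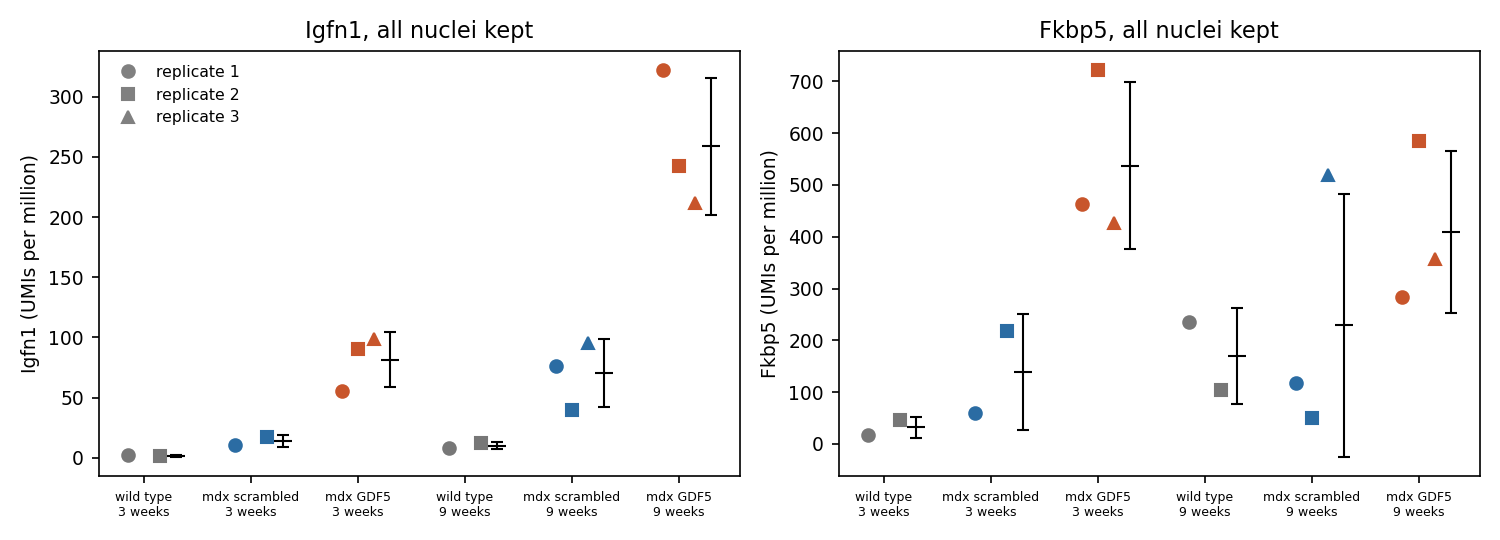
Igfn1 and Fkbp5 in CPM over all nuclei kept, 1 symbol per library, with group means and SD in black. Igfn1 was 55.7 to 98.7 with GDF5 against 10.5 and 17.4 with the scrambled vector at 3 weeks and 212 to 322 against 39.4 to 95.6 at 9 weeks, without overlap, while Fkbp5 overlapped at 9 weeks.

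**Figure D5:**
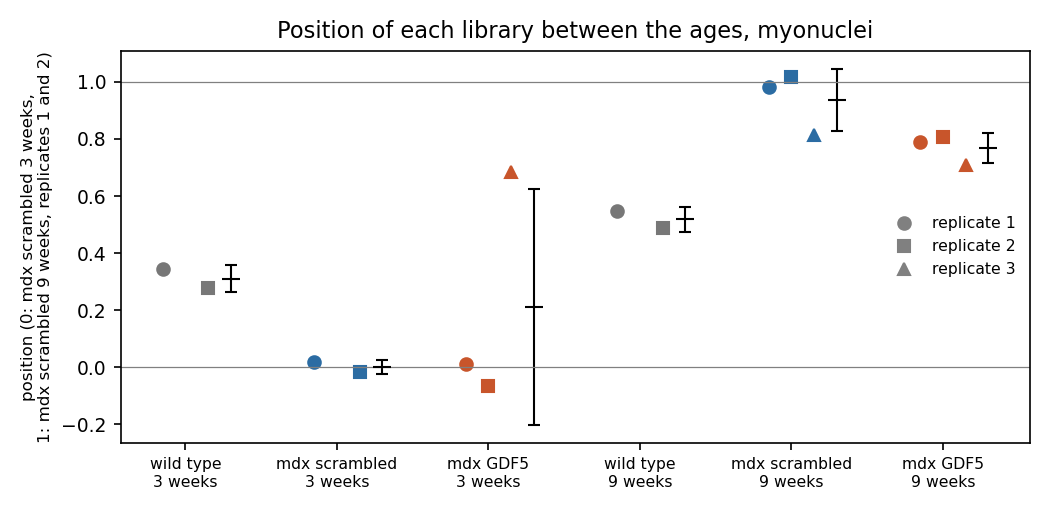
Position of each library between the mean of mdx scrambled muscle at 3 weeks (0) and that of replicates 1 and 2 at 9 weeks (1) over 1178 myonuclear genes, 1 symbol per library. Scrambled replicate 3 at 9 weeks lies at 0.81. Wild-type libraries lie at 0.34 and 0.28 at 3 weeks and at 0.55 and 0.49 at 9 weeks. Replicate 3 of the GDF5 group at 3 weeks lies at 0.69 and the other libraries of that group at 0.01 and −0.07.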

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

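The position on the age axis, the test of free RNA, the comparison of interferon genes within cell classes, the test of sex for glucocorticoid genes, the list of those genes and the counts of other splits were chosen after the result was seen, and so was the rule that a value must clear its spread before it excludes an explanation.

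Barcodes that failed the filters and enter no comparison also carried the Gdf5 transcript, at a mean of 28.75 CPM at 3 weeks and 4.753 CPM at 9 weeks with the GDF5 vector, against 0 of 13540142 and 0 of 13542968 UMIs with the scrambled vector.

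The library of GDF5 replicate 3 at 3 weeks stood apart from the others of its group. Placed over 1178 myonuclear genes between the mdx scrambled mean at 3 weeks (0) and that of replicates 1 and 2 at 9 weeks (1), where scrambled replicate 3 lay at 0.81, it lay at 0.686, its group mates at 0.01 and −0.07 and the 9-week GDF5 libraries at 0.71 to 0.81, so less vector RNA alone, which would leave it near the scrambled 3-week libraries, is argued against. On this axis wild-type libraries lay at 0.34 and 0.28 at 3 weeks and at 0.55 and 0.49 at 9 weeks, so it follows genotype as well as age. A muscle older than its label may account for the position of GDF5 replicate 3 (0.686 where over 0.5 was needed). A constant shift of the libraries numbered 14 to 16, by sex or library batch, stays open, since the displacement of the other 2 libraries along its own was at most 0.2502, between the bounds set for yes and no. No biological explanation was tested, and no other female library was labelled 3 weeks.

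Genes that glucocorticoids raise, such as Fkbp5, Zbtb16 and Tsc22d3, were higher in the GDF5 libraries, with 13 of 13 above 0 in whole muscle at 3 weeks (median 0.54, 0 at an unadjusted p under 0.05) and 13 of 13 at 9 weeks (median 0.74, jackknife SE 0.937, 1 under 0.05), and 12 of 13 in myogenic cells at 9 weeks (median 0.90); at 3 weeks, against 1 scrambled library, the myogenic median was −0.12, or 0.37 without libraries 14 to 16 and 0.12 with sex as a term. Levels were pooled over the 9-week GDF5 libraries. In them progenitors held these genes at a median of 0.823 of their myonuclear level, from 0.108 to 11.65. Myofibre transcripts stood at a median of 0.172, from 0.102 to 0.8245 (Acta1). At that median share, free RNA from myonuclei would not make most of the level of a gene at 0.823. At the highest share, free RNA could make it. Its part in the rise there stays open, since the median of 0.94 lay −0.134 (jackknife SE 0.551) from the sum that free RNA would carry, and subtracting the median or the highest share of myofibre transcripts left 0.74 (SE 0.379) or 0. Time of day is argued against at 9 weeks, because 12 clock genes in whole muscle lay at percentile 11.2 of random lists. At 3 weeks it was not tested. At 9 weeks each group held 1 female library of 3, so a shift by sex common to both groups cannot make the difference. The 9-week whole-muscle median without libraries 14 to 16 was 1.48. At 3 weeks only the GDF5 group held a female library. There the whole-muscle median was 0.67 without those libraries and 0.41 with sex as a term, each with 13 of 13 above 0. An effect of the GDF5 vector and a difference in handling or stress between the mice stay open, and the second cannot be tested here.

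Interferon response genes were lower in the GDF5 libraries at 9 weeks, 25 of 25 in whole muscle (median −0.89, jackknife SE 0.719). Fewer immune nuclei and a single library each stay open, because the values that would exclude them lay within their spread. Each group held 1 female library of 3, so a shift by sex common to both groups cannot make this difference. With sex as a term the median was −0.83, with 25 of 25 below 0. Whether the difference is larger in the female libraries stays open. Within classes the second lowest median was −0.50, with 1 library left out the medians ran from −1.56 (without GDF5 replicate 1) to −0.63 (without scrambled replicate 3), and without libraries 14 to 16 it was −0.54. An effect of the vector on interferon genes stays open too.

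For GDF5 against scrambled at 9 weeks, the 6 libraries make only 10 splits, too few for a share under 0.05. The real split gave 0 genes in whole muscle, myonuclei, myogenic cells, progenitors and macrophages, so 10 of 10 splits gave as many, and the highest of the other splits gave 0, 1, 22, 0 and 0. The split with 22 genes in myogenic cells set GDF5 replicate 3 and scrambled replicates 1 and 3 against the rest, with both female libraries on 1 side. The other splits with both female libraries on 1 side gave 2, 0 and 0 genes there, so what sets the 22 apart was not settled. Among the 4 splits that part all 3 numbered pairs, the highest other count was 0.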

How the results depend on the processing

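The disease by age difference, the sex term, the 20% mitochondrial limit, the doublet score limit of 0.25 in every library and the fits that keep cluster 22 were chosen after seeing the data. The fits without the libraries numbered 14 to 16 were planned for numbers of genes and named genes, and added later for shares, lists, the disease by age difference and together with other settings. The other alternatives were planned. The direction and call of the genes followed one by one stayed the same in 1535 of 1716 tests under other settings, with 58 stronger, 0 reversed and the rest weaker. With 1 library left out, 506 of 681 such tests stayed the same, 169 were weaker, 4 stronger and 2 reversed, the last both for Pax7 in myogenic cells at 9 weeks (0.01 without scrambled replicate 1 and 0.11 without scrambled replicate 2, over a range of −0.26 to 0.11). Where a value below differs from the one reported, the cause was not tested, apart from fewer libraries where libraries were left out. With cluster 22 kept, it held 50 of 82, 50 of 70 and 5 of 299 myogenic nuclei in GDF5 replicates 1 to 3 at 3 weeks. It held 8 of 264 in scrambled replicate 2, the only scrambled library there with at least 20 such nuclei (replicate 1 had 18). Without libraries 14 to 16, gene counts with that cluster kept thus do not separate vector from cluster at 3 weeks or for the interaction. With 2 to 3 libraries a group, small differences are beyond reach: in simulated data 0% to 30% of 2-fold changes were recovered. Leaving out the 1 scrambled library at 3 weeks with enough myogenic or endothelial nuclei left no group to compare and gave no value.

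GDF5 against scrambled, number of genes changed. At 3 weeks the reported counts were 0 in whole muscle, myonuclei, myogenic cells and progenitors, 1 in macrophages and 4 in endothelial cells. DESeq2 gave 4 in whole muscle, 6 in myonuclei, 95 in macrophages and 2 in endothelial cells. Without the libraries numbered 14 to 16, 1 gene passed in whole muscle, 6 in myonuclei, 9 in myogenic cells and 0 in macrophages. The sex term gave 1 in whole muscle and 1 in myonuclei. A fit of the compared groups only gave 0 in macrophages and 2 in endothelial cells, doublets kept gave 0 in macrophages, and the 20% mitochondrial limit gave 0 in macrophages and 0 in endothelial cells. That limit without libraries 14 to 16 gave 1, 7, 0 and 0 in whole muscle, myonuclei, macrophages and endothelial cells. With no filter on low counts, 44 passed in myogenic cells, 11 in progenitors and 212 in macrophages. With cluster 22 kept and without libraries 14 to 16, 620 passed in myogenic cells.

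At 9 weeks the reported counts were 0. DESeq2 gave 13 in whole muscle, 5 in myonuclei, 1 in progenitors and 1 in macrophages. Without libraries 14 to 16, 1 passed in whole muscle, 6 in myonuclei and 74 in myogenic cells. The sex term gave 1, 2, 23 and 1 in whole muscle, myonuclei, myogenic cells and macrophages. The 20% limit without libraries 14 to 16 gave 1, 10, 4 and 1 in the same classes. No filter on low counts gave 36 in myogenic cells, 39 in progenitors, 33 in macrophages and 1 in endothelial cells. A fit of the compared groups only gave 4 in myogenic cells and 3 in progenitors, at least 1000 UMIs gave 1 in myogenic cells, doublets kept gave 1 in macrophages, and cluster 22 kept without libraries 14 to 16 gave 31 in myogenic cells. For the treatment by age interaction, reported as 0, myogenic cells gave 1 with at least 1000 UMIs, 163 with cluster 22 kept and libraries 14 to 16 left out, 50 with no filter, 9 with the sex term and 8 without libraries 14 to 16, and progenitors gave 2 with no filter.

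With the replicate block, the pairs by number gave 22 genes in myogenic cells, 1 in myonuclei and 1 in macrophages at 9 weeks. Where the numbers do not pair the libraries, the block gave 1 in myonuclei, 2 in macrophages and 0 in endothelial cells for GDF5 at 3 weeks, 4 for the interaction in myogenic cells, 50 for age in myonuclei, and 622 in whole muscle and 1234 in myonuclei for mdx against wild type at 3 weeks. The block changed no other call on a number of genes.

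Disease and age, number of genes changed. For mdx against wild type at 3 weeks (312 in whole muscle, 778 in myonuclei), DESeq2 gave 1546 and 1616, the sex term 724 and 1478, and the fit without libraries 14 to 16 869 and 1588. The 20% limit gave 514 in whole muscle, with libraries 14 to 16 left out as well 833 and 1650, and the compared groups only gave 492 in myonuclei. For age in myonuclei (148), DESeq2 gave 1020, the sex term 295, no libraries 14 to 16 1181, the 20% limit 0, that limit without libraries 14 to 16 926, and the compared groups only 297. For age in myogenic cells (225), DESeq2 gave 112, the sex term 423, no libraries 14 to 16 675, the 20% limit 113, that limit without libraries 14 to 16 593, the compared groups only 446, no filter 471, cluster 22 kept 3, and cluster 22 kept without libraries 14 to 16 597. The disease by age difference, reported as 0, was 916 in whole muscle and 30 in myonuclei by DESeq2, 351 and 134 without libraries 14 to 16, and 1 in whole muscle with the sex term. Of the 126 calls on gene lists by camera, 0 held with an estimated correlation, and fry made 23. The estimated correlation called no list in any comparison and was not tried on simulated changes. Its p-values therefore do not show that a list stayed the same.

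Shares of nuclei. For the myogenic share under GDF5 at 3 weeks (reported −0.12), the direction reversed to 0.14 with cluster 22 kept, 0.15 with doublets kept, 0.10 as a difference of log shares, 0.37 at the 20% limit and 0.16 at that limit without libraries 14 to 16. At 9 weeks (−0.20) it reversed to 0.31 without mature myonuclei in the denominator, 0.26 as a difference of log shares and 0.037 at the 20% limit. The myonucleus share at 9 weeks reversed to −0.033 with TMM over classes. The age difference in myogenic share reversed to −0.32 without mature myonuclei in the denominator, and passed at the 20% limit without libraries 14 to 16 (1.34). For mdx against wild type it passed at 3 weeks with TMM over classes (4.95), and at 9 weeks the difference of log shares was 5.84 with an exact permutation p of 0.1, the smallest possible. The number of classes changed at 3 weeks between mdx and wild type went from 0 to 2 with TMM over classes, 4 at the 20% limit and 4 with libraries 14 to 16 left out too, and at 9 weeks from 4 to 7 without mature myonuclei. With age it went from 0 to 1 with cluster 22 kept, doublets kept, the 20% limit, the sex term, no libraries 14 to 16, or cluster 22 kept without those libraries, to 2 without mature myonuclei, and to 4 at the 20% limit without libraries 14 to 16. For GDF5 at 9 weeks that last setting gave 1.

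Leaving out each library in turn gave these ranges of genes changed. For GDF5 at 3 weeks they were 0 to 1 in whole muscle, 0 to 2 in myonuclei, 2 to 8 in myogenic cells, 0 to 1 in progenitors, 0 to 159 in macrophages and 4 to 4 in endothelial cells. At 9 weeks they were 0 to 0 in whole muscle, progenitors and endothelial cells, 0 to 4 in myonuclei, 0 to 5 in myogenic cells and 0 to 1 in macrophages, and for the interaction 0 to 0 in myonuclei and progenitors and 0 to 8 in myogenic cells. For mdx against wild type they were 4 to 117 in whole muscle and 25 to 260 in myonuclei at 3 weeks, and 2495 to 5417 and 272 to 1573 at 9 weeks. For age they were 0 to 0 in myonuclei and 81 to 226 in myogenic cells. Classes changed were 0 to 0 for GDF5 at both ages, 0 to 1 and 2 to 5 for mdx against wild type at 3 and 9 weeks, and 0 to 2 with age. The log2 ratio of myogenic shares ranged from −1.92 to 2.86 and from −0.65 to 1.08 for GDF5 at 3 and 9 weeks, from 2.06 to 9.52 and from 5.19 to 7.41 for mdx against wild type, and from 0.69 to 4.95 with age. The difference in Gdf5 was 20.7 to 39.5 CPM at 3 weeks and 7.22 to 12.7 CPM at 9 weeks.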

Other observations

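The disease by age difference, the tests on cluster 19 and the permutation tests of Igfn1 and Fkbp5 were chosen after their values were seen; the tests of both hypotheses at the end were written before their results.

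A myonucleus cluster of 714 nuclei (cluster 19), 17.5% of them called doublets, was set apart by imprinted noncoding RNAs of 1 locus. Its nuclei not called doublets held 44420 CPM of Meg3, 14580 CPM of Rian and 3246 CPM of Mirg. Those of the largest myonucleus cluster of 3-week mdx muscle (cluster 0) held 218, 38.4 and 7.70 CPM. Gdf5 stood in cluster 19 at 618, 39.5 and 0 CPM in the GDF5 libraries at 9 weeks, on 81, 8 and 0 counts, against 16.4, 12.1 and 4.47 CPM in their other myonuclei. At 3 weeks it stood at 45.9, 36.0 and 0 CPM against 41.8, 39.1 and 3.65 CPM. At 9 weeks the cluster made up 0.337% ± 0.144 (SD, n = 3) of nuclei with the GDF5 vector, from 0.253% to 0.503%, and 0.0192% ± 0.0172 (n = 3) with the scrambled vector, from 0% to 0.0334%. The exact permutation p was 0.1, the smallest possible. At 3 weeks it made up 2.28% ± 1.88 (n = 3) with GDF5, where replicate 3 had 0.258%, and 1.27% ± 0.0127 (n = 2) with the scrambled vector (exact permutation p = 0.6).

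Myostatin RNA had whole-muscle fold changes of opposite sign against wild type at the 2 ages, and neither passed the test. Mstn had a log2 fold change of 2.54 ± 0.64 (SE) in mdx scrambled at 3 weeks and −1.22 ± 0.56 at 9 weeks (adjusted p = 0.0620 and 0.106). In myonuclei these were 2.61 ± 0.59 and −0.50 ± 0.52 (adjusted p = 0.0282 and 0.550). The difference was −3.76 ± 0.84 (adjusted p = 0.132), and in myonuclei −3.11 ± 0.77 (adjusted p = 0.402). Utrn had a difference of 1.27 ± 0.35 in whole muscle and Runx1 of 1.75 ± 0.58 in myonuclei, with adjusted p of 0.134 and 0.429. By edgeR 0 genes differed between the ages in this contrast in whole muscle (3412 at an unadjusted p under 0.05; DESeq2 598 up and 318 down) and 0 in myonuclei (1582; DESeq2 11 and 19).

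Igfn1 and Fkbp5 were tested over both ages at once, with labels of the vector permuted within each age. The exact permutation p was 0.005 for Igfn1, the smallest that 200 combinations allow, with log2 differences of 2.47 and 1.93 at 3 and 9 weeks. For Fkbp5 it was 0.02, with differences of 2.19 and 1.41. Both genes were picked for their values and neither p is adjusted over genes.

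A first hypothesis was that the GDF5 vector may shift mdx myonuclei towards wild type at 9 weeks. The 778 genes that differed between mdx and wild type at 3 weeks came from libraries of their own. Over them the mean log2 change under GDF5 in the direction of the 3-week disease change was −0.130, and 558 genes moved against that direction. The mean was the lowest of the 20 ordered splits of the 6 libraries, the next at −0.0749. Of these genes, 184 of 417 risen and 184 of 361 fallen were called the same way at 9 weeks. The values therefore do not measure the distance to wild type at 9 weeks. These values are differences of mean log2 CPM. Without libraries 14 to 16 the mean of the edgeR log2 fold changes, another measure, was −0.134 and was not ranked among splits. The genes are not independent of one another, and 20 splits cannot give a share under 0.05.

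A second hypothesis, that the same genes may respond to GDF5 at both ages, was left undecided. Across 15713 myonuclear genes the effects at 3 and 9 weeks had a correlation of 0.192, which ranked 43 of 200 ordered splits, with a highest other value of 0.396. Genes are not independent replicates, and without libraries 14 to 16 the correlation was 0.388.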
